A study of Homo sapiens with 4 samples.

How the data were processed

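The series holds 4 arrays of human neural progenitor cells, 2 without treatment and 2 after 72 h with an amine-terminated PAMAM dendrimer at 10 µg/mL, each from Cy3-labelled RNA (50 ng of input, per the labels). Per the file headers, the deposited scanner files were written by Agilent Feature Extraction version 10.7.3.1 for a 1-colour array of human genes annotated on hg19, and they hold spot intensity. The processed intensity is background-subtracted and detrended across the array but not normalized between arrays, and the raw mean and background intensities were deposited beside it, per the file headers. Flags of 0 or 1 mark spots that are well above background, saturated or outliers. The authors also deposited a table of log2 values for the 4 arrays. How it was made is not given in the sources used here. From its values, differences between arrays equalled those of the log2 processed intensity minus its 75th percentile in 100% of 50683 probes, within 0.01 and up to 1 constant per array of at most 0.0439. Each probe was centred on its median, so the absolute level is not known from that table. Its column medians were −0.06, 0.02, −0.01 and 0.03 for control replicates 1 and 2 and dendrimer replicates 1 and 2.

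Each array had 62976 spots, 61657 of them outside the control spots, for 50683 probes. Spots that Feature Extraction marked as non-uniform or as population outliers were set to missing, 0.709% of the spots outside the control spots. The log2 processed intensity minus the array's 75th percentile was averaged over the spots of a probe. A probe was tested if it was well above background on at least 2 of the 4 arrays, whatever their group, where a probe counted as above background if over 0.5 of its spots were. A gene was represented by its tested probe with the highest mean over the 4 arrays, and in named genes with several probes the others are read under the alternatives. Among the printed genes that the naming rule below gives, the probes of NES, MAP2, PAX6, KRT8 and AQP1 disagreed in direction. Genes printed outside that rule were not covered by this comparison of probes. The 84 probes of ERCC transcripts, a set of synthetic control RNAs, were left out after the files were seen, since the files do not mark them as control spots. Gene symbols came from the RefSeq accession of the probe where the reference table held it, for 28174 probes, and otherwise from the file, for 22509 probes. No genome sequence was used here, and probe coordinates are those of the files on hg19.

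Depth on an array is signal over background. Median signals per array lay between 27.5 and 33.9, and the brightest signals between 425900 and 456900. The scanner's own median coefficient of variation (CV) over replicated probes was 4.93%, 4.78%, 6.68% and 6.09% in the order above. Arrays of the same group correlated at 0.986 in both groups across genes, which are not independent replicates, and the SDs of their log2 differences were 0.50 and 0.49. All 4 arrays were scanned as 1 batch in which both controls and then both dendrimer arrays occupy neighbouring positions, so position and group cannot be told apart.

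The comparison of dendrimer with control was fitted with limma version 3.58.1 (lmFit and eBayes, two-sided) in R version 4.3.3, with Benjamini-Hochberg adjustment over 19838 genes and a threshold of 0.05. The equal replicate numbers of the labels are not said to mark shared cultures, so this fit has no block. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333, so none was used. Gene lists were tested with camera in the same fit, with a preset correlation of 0.01, with an estimated correlation beside it, and with Benjamini-Hochberg adjustment over the lists with at least 5 tested members. The median, the mean and the direction of camera agreed in sign in all 30 tested lists. fry, which asks whether the genes of a list move on balance one way and compares them with no other genes, was an alternative.

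All lists were fixed before the data were examined. The 22 gene lists were neural progenitor, neuronal differentiation, synapse and neurotransmitter, axon guidance, S phase and DNA replication, mitosis, p53 targets, apoptosis regulators, immediate early, NRF2 oxidative stress, unfolded protein and integrated stress, heat shock, metallothionein and zinc, cholesterol synthesis, lysosome and autophagy, NF-kB inflammation, interferon, hypoxia and glycolysis, mitochondrial respiratory chain, BMP and TGF-beta targets, WNT targets and ion channels of neurons. The 9 lists of cell type markers were astrocyte, oligodendrocyte lineage, pluripotent, neural crest, mesenchymal and matrix, epithelial, choroid plexus, endothelial, and blood and microglia. Named genes followed a rule fixed at the same time. It takes 12 genes per direction among those past the threshold with both dendrimer arrays on the same side of both controls, filled by the smallest p and said not to pass where too few pass. To these it adds up to 4 members of each list by smallest p and 9 genes in any case (SOX2, NES, PAX6, TUBB3, MAP2, DCX, GFAP, MKI67 and EGR1). The text prints part of the genes that this rule gives.

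Alternatives were other normalizations (quantile, median, 75th percentile of detected probes), normexp background correction with an offset of 50, other filters on dim probes, flagged spots kept, the authors' log2 values, other rules from probes to genes, limma with an intensity trend and robust variance, the replicate number as a block, and each array left out in turn. Where 1 array of a group remained, its spread was taken from the other group. The steps were tested on simulated data for 19838 genes in 2 against 2 arrays, with 200 changed genes. With each gene's own replicate SD, 0% of 67 genes changed 2-fold, 40.3% of 67 changed 4-fold and 63.6% of 66 changed 8-fold were recovered, with 2 false calls. With an equal SD for every gene, 94%, 100% and 100% were recovered. Of 5 simulated lists of 20 genes shifted by 0.5 log2 units all 5 were called, and 1 of 25 unshifted lists was. The simulated genes were drawn independently, so this does not show how often camera calls unshifted lists of correlated genes. In the real data the estimated correlation was 0.78 for cholesterol synthesis and 0.52 for mitosis. Figures were drawn with matplotlib version 3.10.9.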

Results

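Gene expression was measured in human neural progenitor cells (hNPCs), a cell line that grows as undifferentiated neural precursors and forms neurons when growth conditions change. The cells were seeded at 6000 per well to form neurospheres, which are round clusters of neural precursors, and were moved on day 2 to laminin-coated plates in a differentiation medium with 10 ng/mL of brain-derived neurotrophic factor (BDNF). From day 4, 1 group received an amine-terminated polyamidoamine (PAMAM) dendrimer, a branched and positively charged polymer, at 10 µg/mL for 72 h, and the control group received none. RNA was taken from 4 pooled neurospheres, and 2 arrays per group were hybridised with 1 colour (Cy3). The signals at the 75th percentile of the 4 arrays were 507.5 and 471.2 in control replicates 1 and 2, and 465.0 and 457.6 in dendrimer replicates 1 and 2. Between 50.5% and 52.3% of the 50683 probes were well above background on each array, and no spot was saturated. The labels do not say that the arrays came from separate cultures. The p-values of limma below therefore measure only the spread between these samples, which may be technical. With its preset correlation, camera sets the genes of a list against all other genes, so its p-values treat genes rather than arrays as the units. The number of arrays, 2 per group, limits the precision of every value.

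The comparison of dendrimer-treated with untreated neurospheres asked how the polymer affected neuronal differentiation. Immediate early genes, which respond quickly to growth factors and neuronal activity, were lower with the dendrimer: EGR1, a zinc finger transcription factor, was 5.85-fold lower and FOS, a subunit of the AP-1 transcription factor, 2.98-fold lower. Neuronal differentiation genes were higher in 18 of 23 tested members. Among them NHLH1, a transcription factor of newborn neurons, was 1.88-fold higher and DCX, a microtubule-binding protein of migrating neurons, 1.78-fold higher. Mesenchymal and matrix markers, the only list of cell type markers that passed, were lower in 9 of 12. The neural progenitor list did not pass (median log2 difference 0.06, camera adjusted p = 0.0543). Its members had log2 differences such as 0.08 for SOX2, 0.18 for PAX6 and 0.71 for HES5. The immediate early, neuronal differentiation and mesenchymal lists passed camera only with its preset correlation of 0.01. With an estimated correlation no list passed (adjusted p = 0.514 for each of these), and none passed fry (smallest adjusted p 0.146). The estimated correlation was 0.014 for immediate early, −0.017 for mesenchymal and matrix and 0.21 for neuronal differentiation genes. With an estimated correlation, camera takes its degrees of freedom from the arrays, 2 per group, and not from the genes. For the first 2 lists the loss therefore came with this change and not with a high correlation. The unadjusted camera p of immediate early genes went from 1.90e-14 to 0.018. For neuronal differentiation genes both changes applied, and their shares cannot be told apart here. No single gene of the 19838 passed limma at an adjusted p of 0.05.

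At the level of single genes, the smallest adjusted p from limma was 0.290, for TIMP4, an inhibitor of matrix metalloproteinases, and 0 genes passed together with a 2-fold difference. An unadjusted p under 0.05 was reached by 679 genes, of which 278 were higher and 401 lower with the dendrimer, against 991.9 by chance. Without regard to p, 343 genes differed at least 2-fold. Among them, both dendrimer arrays lay above both control arrays for 86 genes and below both for 152 genes. Over all genes the 2 groups did not overlap for 26.7%, where chance gives 33.3%. Both chance values, 991.9 and 33.3%, hold for arrays that are alike but for the group. Here the deviations of same-numbered arrays from their group means correlated at 0.454 across genes, which can lower both observed values. With the replicate number as a block, 1637 genes had an unadjusted limma p under 0.05. Values under chance therefore do not show that the groups differed less than by chance. Without dendrimer replicate 1, limma called 3 genes, all higher, and each rested on the single remaining dendrimer array: EVX2, SBK2 and 1 probe with no gene symbol, chosen for mention after their values were seen.

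The genes with the smallest p on the lower side, none of which passed, included secreted and surface proteins, transcription factors and calcium-binding proteins. They were not tested as a group. ADM, the precursor of the vasodilator peptide adrenomedullin, was 6.11-fold lower, at 1.28 ± 0.27 (SD, n = 2) log2 units relative to the 75th percentile in controls and −1.33 ± 0.25 with the dendrimer. THY1, a surface glycoprotein of neurons and fibroblasts, was 6.08-fold lower (log2 difference −2.60, SE 0.24). IGFBP3, a carrier of insulin-like growth factors, was 5.42-fold lower (log2 difference −2.44, SE 0.20). VGF, a precursor of secreted neuropeptides, was 7.40-fold lower, at 6.35 ± 0.52 in controls and 3.46 ± 0.23 with the dendrimer. CALB1, a calcium buffer of neurons, was 3.58-fold lower and EGR2, a relative of EGR1, 2.46-fold lower. For 5 more genes no dendrimer array was well above background, so only a lower bound of the difference is given, computed against the higher of the probe's own signal and the lowest signal that was well above background on that array. On that basis ETV4 and ETV5, a pair of ETS-family transcription factors, were at least 8.22-fold and at least 3.02-fold lower. The calcium-binding protein S100A11 was at least 3.78-fold lower and TIMP4 at least 2.20-fold lower. The pancreatic elastase gene CELA3A was at least 1.22-fold lower, and its probe may also read its near-identical neighbour CELA3B. These bounds, like all such bounds below, hold for the main processing only. Over the alternatives the smallest log2 differences were −1.50 for ETV4, −0.69 for ETV5, −0.64 for S100A11 and −0.55 for TIMP4.

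Genes with the smallest p on the higher side, none of which passed either, were of several kinds and were not tested as a group. CYP26A1, an enzyme that degrades retinoic acid, was 2.76-fold higher (log2 difference 1.46, SE 0.25). ECEL1, a neuronal membrane peptidase-like protein, was 2.16-fold higher and the dopamine receptor DRD2 2.13-fold higher. KLHL35 was 1.88-fold higher and SRRM4, a regulator of neuronal splicing, 1.85-fold higher. In XKR4, DNAJC12, GFRA4, SIX3 and CXCL1 no control array was well above background. The chemokine CXCL1 was at least 1.81-fold higher, XKR4 at least 1.43-fold and the cochaperone DNAJC12 at least 1.34-fold. The neurotrophic factor co-receptor GFRA4 was at least 1.31-fold higher, and the forebrain homeobox gene SIX3 at least 1.27-fold. Over the alternatives the smallest log2 differences were 0.24 for CXCL1, 0.36 for XKR4, 0.29 each for DNAJC12 and GFRA4, and 0.27 for SIX3. On hg19, the probe of EGR1 lies on chromosome 5 from 137804891 to 137804950, that of ADM on chromosome 11 from 10328780 to 10328839, and that of NHLH1 on chromosome 1 from 160342027 to 160342086. The adjusted p from limma of the genes named in this paragraph and the one before lay between 0.290 and 0.908.

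**Figure D1:**
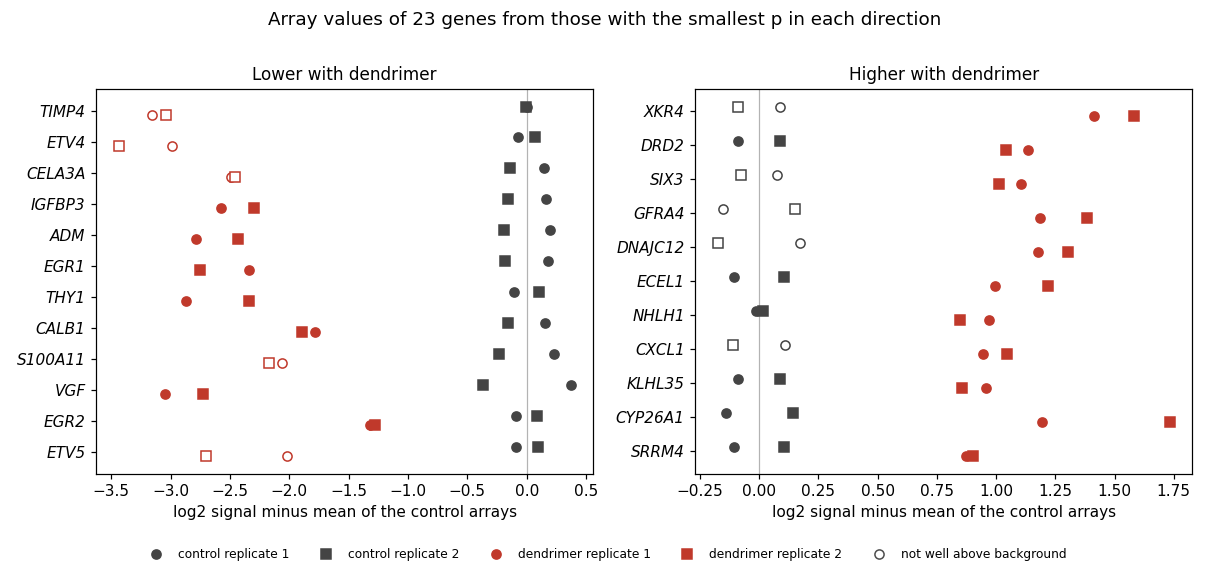
Log2 signal of each of the 4 arrays minus the mean of the 2 control arrays (x axis) for 23 genes (y axis), 12 lower and 11 higher, from those with the smallest p in each direction, with circles for replicate 1, squares for replicate 2, grey for control and red for dendrimer, and open symbols where the probe was not well above background. Both dendrimer arrays lie on the same side of both control arrays for each gene, and none of the 23 passed limma's adjusted p of 0.05, the smallest being 0.290.

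Of 30 gene lists with enough tested members, 9 passed camera at an adjusted p of 0.05 with its preset correlation of 0.01, 3 of them higher and 6 lower with the dendrimer. No list passed camera with an estimated correlation, where the smallest adjusted p was 0.514 and 2 lists had an unadjusted p under 0.05, and none passed fry, where the smallest adjusted p was 0.146. With each array centred on its median, 1 list passed as higher and 6 as lower. Without control replicate 2, 5 lists passed, and without dendrimer replicate 1, 5 lists passed. No member of any list passed limma's test over all genes, and the counts adjusted over the list alone are given with each list. The median of no list changed when the genes dim in a whole group were set to their bound. Most lists held no such gene, so for them no change was possible. The immediate early list held the most, 5, and all of these stayed below its median. The unchanged medians are therefore no test of stability.

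Immediate early genes formed the list with the smallest p. Of its 25 tested members 22 were lower, with a median log2 difference of −0.44 (camera adjusted p = 5.69e-13, and adjusted p = 0.514 with an estimated correlation), and 9 were lower when adjusted over the list alone against 0 over all genes. EGR1 had a level of 4.21 ± 0.25 in controls and 1.66 ± 0.29 with the dendrimer (n = 2 each). FOS was 2.98-fold lower, EGR2 was 2.46-fold lower, and ARC, a regulator of synaptic strength induced by activity, was at least 2.11-fold lower. Over the alternatives the smallest log2 difference of ARC was −0.42. Without dendrimer replicate 2 the median of the list was −0.72, and without dendrimer replicate 1 it was −0.33, with 17 of 25 lower. Normexp background correction gave medians of −0.21 with quantile normalization and −0.17 with the 75th percentile.

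Neuronal differentiation genes were higher as a list. Of 23 tested members 18 were higher, with a median log2 difference of 0.60 (camera adjusted p = 1.20e-11, and adjusted p = 0.514 with an estimated correlation), and 9 were higher when adjusted over the list alone against 0 over all genes. Among them, NHLH1 was 1.88-fold higher and NEUROG1, a proneural transcription factor, 1.86-fold higher. DCX was 1.78-fold higher, from 2.36 ± 0.18 to 3.19 ± 0.02 log2 units (n = 2 each), and NEFM, a subunit of neurofilaments, was 1.70-fold higher. The general neuronal markers TUBB3 and MAP2 had log2 differences of 0.22 each (SE 0.22 and 0.14), neither past the list's own adjustment. GAP43, a growth cone protein named after its value was seen, went the other way at 1.80-fold lower. With normexp the median of the list was 0.28 under quantile and 0.30 under 75th percentile normalization. It was 0.33 with the mean of a gene's probes and 0.77 without control replicate 2.

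Neural progenitor genes did not pass as a list, with 14 of 16 tested members higher, a median log2 difference of 0.06 and a camera adjusted p of 0.0543. NES, an intermediate filament of progenitors, had a log2 difference of 0.05 (SE 0.14), which changed sign with normexp background correction and quantile normalization and without control replicate 2. HES5, a target of Notch signalling, was 1.64-fold higher and LFNG, a modifier of Notch receptors, 1.16-fold higher. Genes of synapses and neurotransmitters were higher as a list, with 14 of 19 tested members higher and a median log2 difference of 0.17 (camera adjusted p = 0.0439, and adjusted p = 0.514 with an estimated correlation). SLC32A1, the vesicular transporter of GABA and glycine, was 1.60-fold higher, SYT4, a synaptotagmin, 1.63-fold and the glutamate receptor subunit GRIA2 1.25-fold. This call was lost when any 1 of the 4 arrays was left out, with camera adjusted p between 0.125 and 0.210 and a median of 0.10 without dendrimer replicate 2, and was also lost with median centring (0.0563) and with no filter on dim probes (0.165). Ion channels of neurons did not pass (10 of 13 higher, median log2 difference 0.12, camera adjusted p = 0.0624), with the calcium channel subunit CACNA1B 1.39-fold higher. Axon guidance genes did not pass either (17 of 25 higher, median 0.16, camera adjusted p = 0.161), and went both ways: the guidance ligands SLIT1 and SLIT3 were 1.44-fold and 1.39-fold higher, the receptor EPHA4 1.30-fold higher and the netrin receptor UNC5C 1.39-fold lower.

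WNT target genes passed as higher, with 5 of 8 tested members higher and a median log2 difference of 0.14 (camera adjusted p = 0.0459, and adjusted p = 0.514 with an estimated correlation). AXIN2, a feedback inhibitor of WNT signalling, was 1.46-fold higher, though its other tested probe had a log2 difference of only 0.11. APCDD1, another inhibitor, was 1.29-fold higher and the transcription factor LEF1 1.27-fold. This call too was lost without any 1 of the 4 arrays, with camera adjusted p between 0.125 and 0.383 and medians of 0.33 without control replicate 2 and 0.25 without dendrimer replicate 2, and was also lost with median centring (0.0801), with the authors' values (0.0587), with normexp (0.102 under both normalizations) and with no filter on dim probes (0.105). Targets of BMP and TGF-beta did not pass (9 of 13 higher, median 0.08, camera adjusted p = 0.567), with ID1 1.23-fold higher and INHBA 1.18-fold lower.

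Mesenchymal and matrix genes were lower as a list, in 9 of 12 tested members, with a median log2 difference of −0.35 (camera adjusted p = 8.41e-05, and adjusted p = 0.514 with an estimated correlation). Adjusted over the list alone, 2 members were lower against 0 over all genes: THY1, and TFPI2, a secreted inhibitor of serine proteases, which was 4.94-fold lower. The fibrillar collagen COL3A1 was 1.58-fold lower and LUM, a proteoglycan of collagen fibres, went the other way at 1.62-fold higher. The interferon list was lower in 9 of 13 tested members, with a median of −0.37 (camera adjusted p = 0.000624, and adjusted p = 0.514 with an estimated correlation), and no member passed adjusted over the list alone. IFITM1, an antiviral membrane protein, was 1.92-fold lower, and IFIT2 and MX1, both induced by interferon, were at least 1.46-fold and at least 1.48-fold lower. Over the alternatives their smallest log2 differences were −0.26 for IFIT2 and −0.13 for MX1. Without dendrimer replicate 1 the median of this list was −0.17. Hypoxia and glycolysis genes were lower in 14 of 19 tested members, with a median of −0.11 (camera adjusted p = 0.00282, and adjusted p = 0.514 with an estimated correlation). ADM and IGFBP3 were the 2 members lower when adjusted over the list alone, against 0 over all genes, while the glycolytic enzyme HK2 was 1.28-fold lower. This call was lost without control replicate 2 (median −0.06, camera adjusted p = 0.119) and without dendrimer replicate 1 (10 of 19 lower, median −0.05, camera adjusted p = 0.232), and the median was −0.18 without control replicate 1 and without dendrimer replicate 2.

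Cell division genes were slightly lower. All 26 tested members of the mitosis list were lower, with a median log2 difference of −0.14 (camera adjusted p = 0.000342, and adjusted p = 0.610 with an estimated correlation), though 23 of 26 were lower with each array centred on its median. No member passed adjusted over the list alone: the proliferation marker MKI67 and the spindle protein ASPM were 1.20-fold lower each, and the mitotic kinase AURKB 1.17-fold lower. Without control replicate 2 the call was lost, with 20 of 26 lower and a median of −0.06 (camera adjusted p = 0.269), as it was without dendrimer replicate 1, with 19 of 26 lower and a median of −0.05 (camera adjusted p = 0.383), and the median was −0.23 without dendrimer replicate 2. S phase genes did not pass (21 of 24 lower, median −0.09, camera adjusted p = 0.0624), with CDC45, a part of the replicative helicase, 1.23-fold lower and RRM2, a subunit of ribonucleotide reductase, 1.21-fold lower. Cholesterol synthesis genes passed as lower, in 20 of 24 tested members, with a median of −0.14 (camera adjusted p = 0.0459, and adjusted p = 0.773 with an estimated correlation). Among their enzymes SC5D was 1.27-fold lower, FDPS 1.19-fold and MVD 1.16-fold. The median of this list was 0.12 without dendrimer replicate 1 and 0.02 without control replicate 2, so its direction rested on these arrays, and the call was also lost with median centring and with the authors' values (camera adjusted p = 0.0563 and 0.0587).

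**Figure D2:**
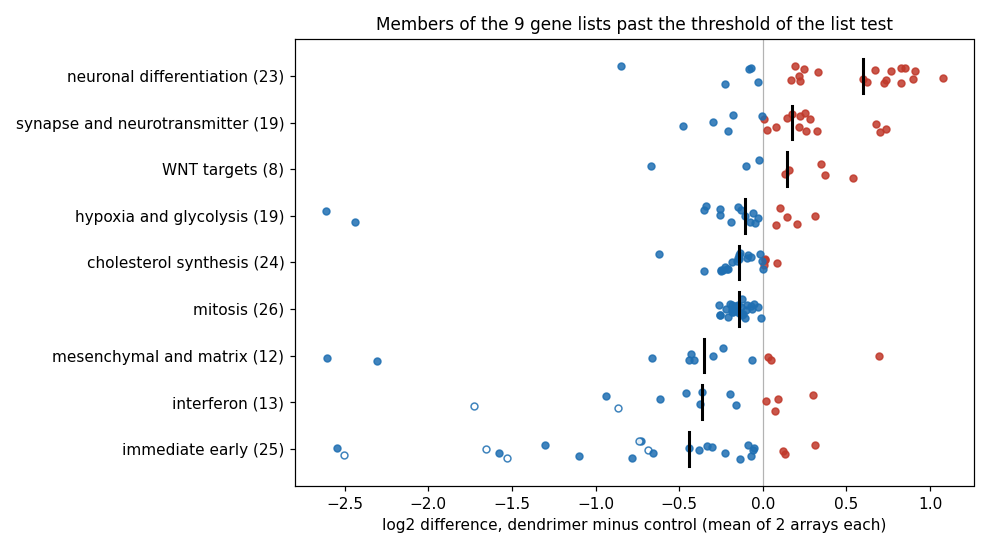
Log2 difference between the mean of the 2 dendrimer arrays and the mean of the 2 control arrays (x axis) for each tested member of the 9 lists that passed camera (y axis, with the number of tested members), in red above 0 and blue below it, with open circles where no array of 1 group was well above background and a black bar at the list's median. The medians run from −0.44 for immediate early genes to 0.60 for neuronal differentiation genes, and all 26 mitosis genes lie below 0 by small amounts (23 of 26 with each array centred on its median).

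Genes that respond to damage and stress did not pass as lists in the main processing. Unfolded protein and integrated stress genes nevertheless passed in 14 of 22 alternatives, with medians from −0.31 to 0.07. The unfolded protein and integrated stress list was lower in 16 of 22 tested members (median −0.15, camera adjusted p = 0.0535), with the amino acid transporter SLC7A5 1.40-fold lower, the pseudokinase TRIB3 1.36-fold and CHAC1, which degrades glutathione, 1.22-fold. Targets of p53 were split, with 10 higher and 12 lower (median −0.01, camera adjusted p = 0.703), and the cell cycle inhibitor CDKN1A was 1.42-fold lower and the stress cytokine GDF15 1.26-fold lower. Apoptosis regulators (median −0.03, camera adjusted p = 0.381) included PMAIP1, a BH3-only promoter of cell death, at 1.26-fold lower. Oxidative stress genes under NRF2 had a median of −0.03 (camera adjusted p = 0.200), with the quinone reductase NQO1 at least 1.71-fold lower. The smallest log2 difference of NQO1 over the alternatives was −0.19. Heat shock genes (median 0.03, camera adjusted p = 0.788) included HSPA4L at 1.24-fold higher. Metallothionein and zinc genes had a median of 0.11 (camera adjusted p = 0.567), with the zinc transporter SLC39A10 1.08-fold higher. Lysosome and autophagy genes (median −0.01, camera adjusted p = 0.763) included the lysosomal channel MCOLN1 at 1.37-fold lower, and mitochondrial respiratory chain genes had a median of 0.04 (camera adjusted p = 0.489). The NF-kB inflammation list did not pass as a whole (6 of 9 lower, median −0.28, camera adjusted p = 0.0720), but 3 of its members passed adjusted over the list alone, against 0 over all genes. These were TNFAIP3, an inhibitor of NF-kB signalling, at 2.41-fold lower, RELB, an NF-kB subunit, at 1.85-fold lower, and CXCL1, which was higher. TNFAIP3 was not well above background on dendrimer replicate 1, and its smallest log2 difference over the alternatives was −0.36.

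Markers of other cell types did not pass as lists, apart from the mesenchymal and matrix list. Endothelial markers were lower in 5 of 6 (median −0.40, camera adjusted p = 0.0720). Among them KDR, a receptor of vascular endothelial growth factor, was at least 2.53-fold lower and was the 1 member past the adjustment over the list alone, against 0 over all genes. Its smallest log2 difference over the alternatives was −0.60. Epithelial markers were higher in 4 of 6 (median 0.35, camera adjusted p = 0.0680), with log2 differences of 0.58 for the adhesion molecule EPCAM and 0.47 for the keratin KRT8. Oligodendrocyte lineage markers had a median of 0.21 (camera adjusted p = 0.110), with MOG 1.26-fold higher, and astrocyte markers one of 0.16 (camera adjusted p = 0.219), with SPARCL1 1.51-fold higher. GFAP, the classical astrocyte filament, was below the detection minimum and was not tested. Pluripotent markers (median −0.31, camera adjusted p = 0.258) included DNMT3B at 1.24-fold lower. Neural crest markers were higher in 3 of 5 (median 0.16, camera adjusted p = 0.763), and TWIST1, 1 of the 2 lower members, was 1.38-fold lower. Blood and microglia markers had a median of 0.02 (camera adjusted p = 0.36), with TYROBP 1.11-fold higher. The choroid plexus list had only 3 tested members and was not tested, with AQP1 1.34-fold higher and FOLR1 1.34-fold lower. In the lists with no count given here, no member passed adjusted over the list alone.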

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

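All tests of explanations in this part were chosen only after the results were seen. The spike-in spots, replicate spots of control RNA that entered no comparison, varied more on the dendrimer arrays than on the control arrays. Their median CV was 8.95% on dendrimer replicate 1 and 9.64% on dendrimer replicate 2, against 3.41% and 3.30% on the control arrays, and the scanner software placed 1 quality metric of each dendrimer array outside its range.

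The dendrimer arrays also held more lone bright spots, over 2 log2 units above the same spot on each of the other arrays: 114 and 72, against 37 and 42 on the control arrays. Of these, 66.7% and 34.7% had another such spot within 2 rows and 2 columns, where the highest of 1000 random placements gave 12.3% and 15.3%, and control replicates 1 and 2 also showed the excess (16.2% and 54.8%, against 10.8% and 14.3%). Transcripts induced by the dendrimer in 1 culture would brighten the other copies of a repeated probe. This held for 0 of 26 such spots on the dendrimer arrays, against 7 of 18 on the control arrays. The 26 were part of 186 lone bright spots on the dendrimer arrays, and the rest could not be checked in this way. The values are consistent with local marks on the array surface, which would also widen the spread of single genes. With probes that had 1 array over 2 log2 units apart from the others left out, limma still called 0 genes, with 687 at an unadjusted p under 0.05.

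Arrays with the same replicate number resembled each other more than arrays of the same group did. The SD of log2 differences across genes was 0.43 between control and dendrimer replicate 1 and 0.39 between control and dendrimer replicate 2, against 0.50 and 0.49 within the groups. Among the 3 ways to split the arrays into 2 and 2, the split by number gave 3826 genes at an unadjusted limma p under 0.05 against 679 for the real split, which points to a structure of the samples, and called 6 lists against 9. Its medians for mitosis (0.16) and cholesterol synthesis (0.34) were larger in size than those between dendrimer and control, −0.14 each. The spike-in level relative to the array was higher on number 2 than on number 1 by 0.83 in controls and 0.64 (0.636) with the dendrimer. It was also higher with the dendrimer (log2 5.10 and 5.74) than in controls (4.63 and 5.46). Labelling yield or spike-in dose may therefore have differed between the numbers and between the groups, and these values cannot tell the 2 apart. Separate cultures per number, which the labels neither state nor exclude, stay open.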

How the results depend on the processing

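The alternatives that combine the replicate block with other settings, and the one without lone bright probes, were chosen after seeing the data. limma called 0 genes, and 0 genes at least 2-fold, under every alternative but 2: 3 genes without dendrimer replicate 1 (range 0 to 3 over the arrays left out in turn, all 3 at least 2-fold), and 83 genes (32 higher, 51 lower, 29 at least 2-fold) with the replicate block together with trend and robust variance. The count of lists, 9, ranged from 7 to 13 over the other planned settings and from 5 to 11 with 1 array left out, was 14 with the replicate block together with trend and robust variance, and was 0 by camera with estimated correlation and 0 by fry. In paired terms, the replicate block alone left 0 genes (1637 at an unadjusted p under 0.05, against 679) and 11 lists, without WNT targets (camera adjusted p = 0.0625), and the deviations of same-numbered arrays from their group means correlated at 0.454 across genes. The labels do not say that the numbers mark pairs. The lists of immediate early, neuronal differentiation, mesenchymal and matrix, and interferon genes passed in 20 of 22 alternatives, failing only with an estimated correlation and by fry, and their medians lay from −0.72 to −0.17, 0.28 to 0.77, −0.41 to −0.25 and −0.48 to −0.08. Mitosis and hypoxia and glycolysis passed in 18 of 22, cholesterol synthesis in 16, synapse and neurotransmitter in 14 and WNT targets in 9, and their adjusted p from camera and fry reached 0.610, 0.514, 0.992, 0.514 and 0.514. Lists that did not pass came past the threshold in 51 cases, led by unfolded protein and integrated stress (14 alternatives) and S phase (12).

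Of the named genes, 26 came past the threshold under 1 alternative each, EVX2 and SBK2 without dendrimer replicate 1 and all others under the added block with trend and robust variance. With 1 value per gene and alternative, direction was kept except in NES, EVX2 and SPARC. Taken singly, the probes of MAP2 (−0.084 to 0.22), PAX6 (−0.043 to 0.18), KRT8 (−0.022 to 0.47) and AQP1 (−0.13 to 0.43) also disagreed in direction. NES was −0.054 with normexp and quantile normalization and ranged from −0.0057 (without control replicate 2) to 0.10 (without control replicate 1). EVX2 ranged from −0.046 (without dendrimer replicate 2) to 5.99 (without dendrimer replicate 1), and SPARC from −0.16 (without dendrimer replicate 2) to 0.23 (without dendrimer replicate 1).

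Of the lists, 11 reversed direction in camera under some alternative. With 1 array left out, medians ranged from −0.24 to 0.081 for S phase and DNA replication, −0.074 to 0.029 for p53 targets, −0.21 to 0.054 for NRF2 oxidative stress, −0.11 to 0.068 for heat shock, −0.14 to 0.23 for metallothionein and zinc, −0.32 to 0.12 for cholesterol synthesis, −0.044 to 0.084 for lysosome and autophagy, −0.092 to 0.15 for mitochondrial respiratory chain and −0.083 to 0.63 for neural crest. Heat shock also reversed in camera, though its median did not, with quantile normalization (0.016), with normexp and quantile normalization (0.035), with no filter on dim probes (0.025) and with each probe on its own (0.022). With no filter the medians of BMP and TGF-beta targets and of blood and microglia were 0.043 and −0.0069, and with each probe on its own that of lysosome and autophagy was 0.013.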

Other observations

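Every test in this part was chosen only after the result was seen. Outside the fixed lists, NID1, which links laminin to collagen in basement membranes, was 2.05-fold lower (log2 difference −1.04, SE 0.14), and the laminin chains LAMC1 and LAMB1 were 1.92-fold and 1.88-fold lower. Over the alternatives the smallest log2 differences were −0.87 for LAMC1 and −0.50 for LAMB1. STMN4, a neuronal relative of stathmin, was 1.85-fold higher. These 4 genes were picked after their values were seen, so they stand for no group of genes, and none passed limma over all genes (adjusted p = 0.863 for the first 3 and 0.924 for STMN4).

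Whether the lower immediate early genes came from lower output of ERK signalling, the kinase cascade downstream of BDNF and other growth factors, stays open. Of 10 genes that report ERK activity, a list chosen because ETV4, ETV5 and the immediate early genes were low, the 6 left without these had 4 lower and 2 higher members and a median log2 difference of −0.40. SPRY4 was 2.81-fold and SPRY2 1.77-fold lower, while CCND1 and EPHA4 went the other way at 1.29-fold and 1.30-fold higher, and no gene passed limma over all genes. Fewer matrix-producing cells stay open too. The 6 matrix genes looked at for this all belong to the mesenchymal and matrix list, so they are no separate check. Neural cells may also express them, and not all were abundant here. They had a median of −0.15 (−0.152) and ranged from −0.66 to 0.05. Values were 0.03 for SPARC at a control level of 4.32, −0.29 for COL1A2 at 2.27 and −0.66 for COL3A1 at −2.40. The position of the arrays on the slide cannot be told apart from the group.

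The count of 9 lists for dendrimer against control compares with a highest count of 6 in the other splits, and only 1 of the 3 splits, the real one, reached 9. With 3 splits a share under 0.05 cannot be had.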
